A study of Homo sapiens with 8 samples.

How the data were processed

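Libraries were poly(A) complementary DNA libraries of DLD1 cells read by paired-end sequencing, per the labels' protocols. The deposited values were FPKM, which normalize each library to its own total and each gene to its length. The aligner TopHat2 2.1.1, the FPKM estimator Cufflinks 2.2.1 and the hg19 genome build were used, per the submitters' processing notes, with no settings given in the sources used here. The gene annotation behind the FPKM was not given in the sources used here. The table held 11638 genes and 8 library columns, and 0 per-sample columns were left unmapped. Its lowest value was 1 FPKM, held by 699 to 2059 genes per library, so values under 1 appeared to have been set to 1 before deposit. No gene was at this value in all 8 libraries, so genes under 1 FPKM throughout appeared to have been left out. The labels state neither step. Read counts and depth were unknown, so no count model was used and no counting error could be given. Of the genes, 8828 lay above the floor in all libraries, and 9 symbols were written as dates, as spreadsheet software does. Gene symbols were kept as listed, with IL8 for CXCL8, IL29 for IFNL1 and TMEM173 for STING1. IL6 and the cGAS gene were not listed. An unlisted gene may have been under 1 FPKM in every library.

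The authors' FPKM were transformed here to log2(FPKM + 1), the pseudocount of 1 understating the change of low genes. The filter of at least 1 FPKM in at least 2 libraries removed 0 genes because of the floor. All 8 libraries entered 1 fit in limma 3.58.1 (R 4.3.3) with 4 group means and 4 residual degrees of freedom, with a trend on mean expression and a robust prior. Each of 5 contrasts was tested two-sided: HU against water in each genotype, knockout against wild type in water and after HU, and the difference of the HU effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. An exact permutation test of 2 libraries against 2 could not reach that threshold. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels do not give clones.

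Before the data were examined, 24 gene lists, the tests, the named genes and most alternative settings were fixed, and 19 lists had at least 5 measured members. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 95 tests, and again with an estimated correlation. With the preset 35 of the 95 tests passed, and with the estimated correlation 0 passed. Interferon genes had 2 measured members (IFNB1 and IL29) and immune cell markers 4 (CD68, LYZ, FCER1G and CD14), no immune cell marker changed in any contrast (1 in water when adjusted over the list alone), and neither list was tested as a set. Replication-dependent histone, mitochondrially encoded and fibroblast genes had 0 listed members. Named genes were a fixed panel, up to 6 of the largest rises and 6 of the largest falls per contrast among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM, and up to 3 members per list with the smallest p. Clone, read-through and small RNA names were left out of the largest changes, and some named genes are not reported here. Pseudogenes and near-identical paralogs are reported as uncertain, since the assignment of shared reads was not given in the sources used here.

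Transcript GC content and length came from GENCODE 29 transcripts by symbol. Symbols matched for 11125 genes (95.6%), 796 of them through an older symbol, and no genome coordinates were used because the reference build differed from the authors' build. Each library's trend on GC content and length was fitted with splines of 4 degrees of freedom and removed, as an alternative chosen after seeing the data. The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile normalization, median-of-ratios scaling, a plain variance prior, the replicate number as a block, a fit of only the groups compared, an estimated correlation, and each library left out in turn. A group left with 1 library was assumed to vary like the others. Outside the fixed panel, named genes were chosen by small p or large change in the same comparison. The share of them that kept a call is therefore favoured in advance and does not give the stability of all calls.

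The test was tested on simulated data in 10 runs, with 100 genes changed per fold size among 11638, in wild-type HU alone. Each gene kept its mean and the spread estimated by the fit, equal in all 8 libraries and independent between genes. The real groups differed in spread and in GC trend, so the rates hold only for data that meet the assumptions of the fit. For the HU effect in wild-type cells it recovered 77.9% of genes changed by 1 log2 unit and 98.4% of those changed by 2, with 8.8 false calls per run. For the difference of the HU effects it recovered 31.9% and 92.7%, with 7.3 false calls. Plots were drawn with matplotlib 3.10.9.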

Results

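RNA of DLD1 cells, an established human colorectal carcinoma line, was measured in 8 libraries that formed 4 groups of 2. Wild-type cells and cells with a CRISPR knockout of IRF3 were each given water or hydroxyurea (HU), an inhibitor of ribonucleotide reductase that stalls DNA replication. The dose was 1 mM for 24 h, and the cells then grew for 5 days without it. IRF3 is the transcription factor that carries signals of the DNA sensor pathway cGAS-STING to interferon genes. The title of the series places it beside RB and senescence, so the comparisons ask which genes responded to HU in each genotype and whether IRF3 loss altered that response. FPKM values were listed for 11638 genes, and values under 1 FPKM appeared to have been set to 1, so a fold against a group at this floor is a lower bound. Sequencing depth was unknown. The number of genes at the floor ranged from 699 in knockout water replicate 2 to 2059 in knockout HU replicate 1.

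The 8 libraries did not vary by group alone. The median difference between replicates was 0.24 log2 units in wild-type water, 0.11 in wild-type HU, 0.25 in knockout water and 0.12 in knockout HU. The first principal component held 61.4% of the variance and set the knockout HU libraries, both at 53.3, apart from all others. Knockout water replicate 1 lay at −2.24 on it and replicate 2 at −28.3, close to the wild-type water libraries at −29.2 and −29.1. Expression also shifted with the GC content of transcripts. Among the fifth of genes with the most GC-rich transcripts, the median deviation from the gene mean was −0.36 and −0.41 log2 units in the knockout HU libraries. It was 0.09 and 0.47 in knockout water, 0.21 and −0.10 in wild-type water, and −0.03 and 0.03 in wild-type HU.

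**Figure D1:**
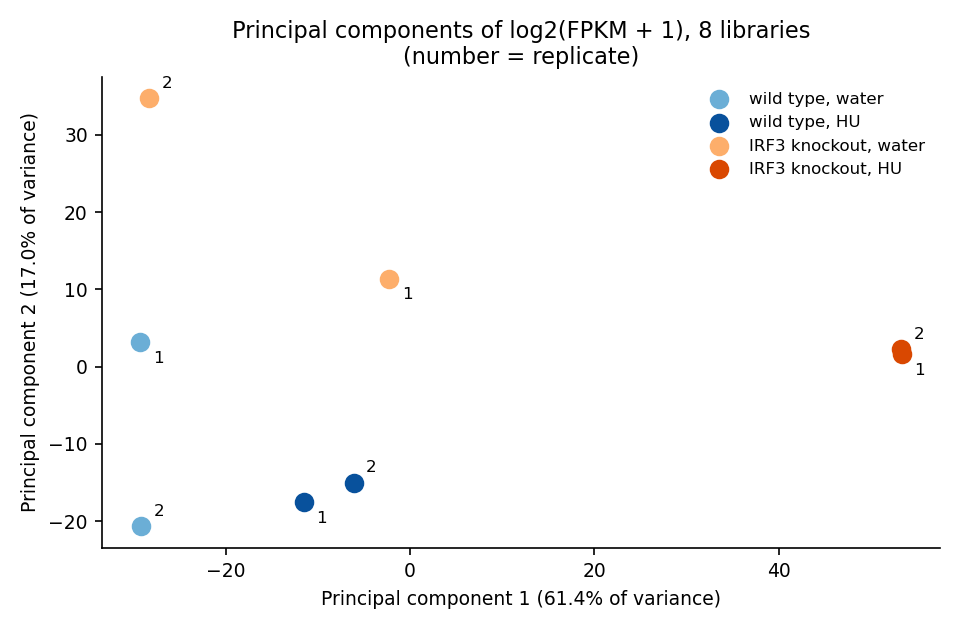
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1), which held 61.4% and 17.0% of the variance; colour marks the group and the number the replicate. Both knockout HU libraries lie at 53.3 on the first component, and the knockout water libraries lie apart at −2.24 and −28.3.

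**Figure D2:**
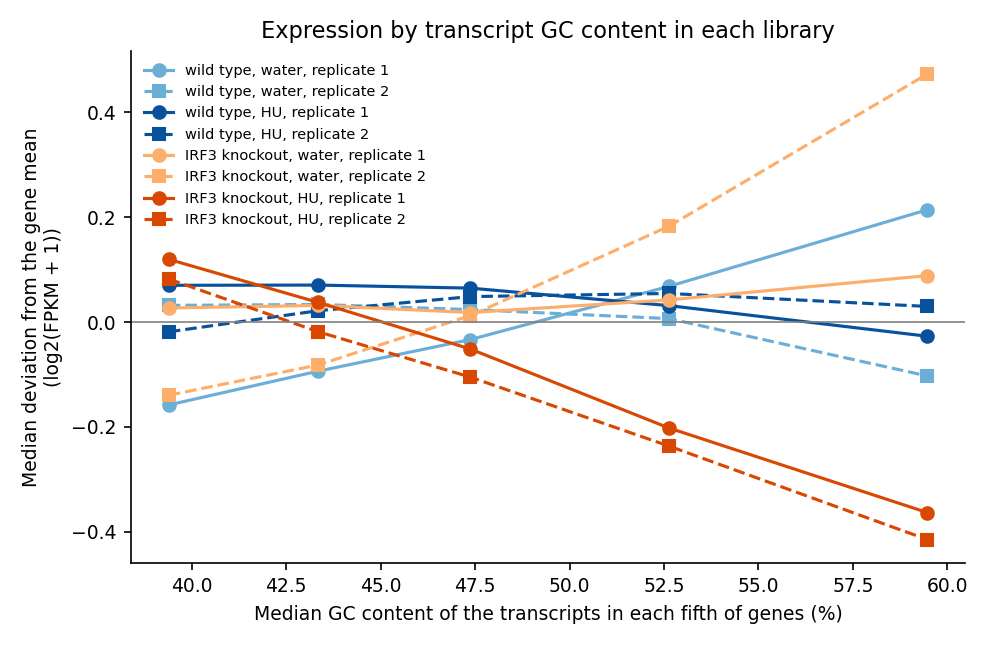
Median deviation from the gene mean, in log2(FPKM + 1), for genes ordered and divided by the GC content of their transcripts, 1 line per library. In the genes richest in GC the knockout HU libraries lie at −0.36 and −0.41 and knockout water replicate 2 at 0.47.

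IRF3 RNA was measured first, as a check of the genotype labels. It stood at 28.3 and 23.1 FPKM in the wild-type water libraries, 26.8 and 31.8 in wild-type HU, 18.5 and 18.1 in knockout water, and 9.11 and 11.6 in knockout HU. All 4 knockout libraries lay below all 4 wild-type libraries. The genotype difference in water did not pass the test (log2 change −0.46, SE 0.17, limma adjusted p = 0.208), while that after HU did (−1.42, SE 0.17, adjusted p = 0.00226). A gene's FPKM does not show a CRISPR edit, so these values check the labels only in part.

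In wild-type cells, HU raised 6 of 39 measured interferon-stimulated genes and 3 of 29 senescence-associated secretory genes. ISG15, a ubiquitin-like antiviral protein, rose from 534 ± 106 FPKM in water to 1264 ± 142 after HU (mean ± SD, n = 2 libraries per group; log2 change 1.25, SE 0.15, limma adjusted p = 0.011). ISG20, an antiviral exonuclease, rose from 8.19 to 36.2 FPKM (log2 change 2.04, SE 0.19), and RSAD2, the antiviral protein viperin, rose from 1.31 to 7.80 FPKM (1.92, SE 0.16). CXCL10, a chemokine that attracts T cells, rose from 2.97 to 9.01 FPKM (adjusted p = 0.0297). IL29, which encodes interferon lambda 1, was at the floor in water and at least 2.89-fold higher after HU (adjusted p = 0.00871). IFNB1, the interferon beta gene, reached 1.66 FPKM from the floor without passing the test (adjusted p = 0.0658). IFIT1, an RNA-binding antiviral protein, stood at 48.8 and 79.7 FPKM (adjusted p = 0.387). Of ISG15, ISG20, RSAD2, CXCL10 and IL29, RSAD2 alone passed in each fit that left out 1 library. Of 39 measured interferon-stimulated genes 6 rose, 0 fell and 33 did not pass, and 17 passed when adjusted over the list alone. The list shifted upward (median log2 change 0.31, camera adjusted p = 5.35e-04), a call lost at adjusted p = 0.32 with an estimated correlation.

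Among 29 senescence-associated secretory genes 3 rose and 0 fell after HU in wild-type cells, with 7 passing when adjusted over the list alone. CSF2, the growth factor GM-CSF, rose from 3.52 to 15.3 FPKM, the chemokine CCL20 from 34.4 to 129 FPKM and CCL5 from 2.28 to 8.36 FPKM. IL8 stood at 41.9 and 77.7 FPKM (adjusted p = 0.0891). The list shifted upward (camera adjusted p = 0.0026, and adjusted p = 0.722 with an estimated correlation). Without wild-type water replicate 1 its camera adjusted p was 0.0861. Of 21 NF-kB targets 2 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 1.89e-04, and adjusted p = 0.722 with an estimated correlation). These were SOD2, mitochondrial superoxide dismutase, from 92.7 to 188 FPKM, and BIRC3, an inhibitor of apoptosis, from 2.2 to 8.22 FPKM. Of 26 integrated stress response genes 2 rose (5 adjusted over the list alone; camera adjusted p = 0.384). These were the transcription factors DDIT3, from 69.0 to 189 FPKM, and ATF3, from 3.45 to 14.5 FPKM. B2M, the light chain of MHC class I, rose 2.14-fold as the 1 changed gene of 20 in class I presentation (2 adjusted over the list alone; camera adjusted p = 0.448).

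The list of DNA replication genes shifted downward with the preset correlation. Of 53 G1/S and replication genes 2 fell and 0 rose (18 adjusted over the list alone; median log2 change −0.33, camera adjusted p = 3.21e-15, and adjusted p = 0.24 with an estimated correlation). CDC45, part of the replicative helicase, fell from 57.2 to 33.4 FPKM (log2 change −0.76, SE 0.13, limma adjusted p = 0.0382) and MCM4, another subunit of it, from 67.4 to 42.7 FPKM. Neither passed in any fit that left out 1 library (adjusted p up to 0.279 for CDC45 and 0.318 for MCM4), and MCM4 had adjusted p = 0.0574 after median-of-ratios scaling. None of the 32 homologous recombination and Fanconi genes passed limma (0 adjusted over the list alone), with a list median of −0.16 (camera adjusted p = 9.68e-05, and adjusted p = 0.573 with an estimated correlation). The same held for 50 mitotic genes (0 adjusted over the list alone; median −0.13, camera adjusted p = 0.00339, and adjusted p = 0.722 with an estimated correlation) and for 15 Wnt targets (1 adjusted over the list alone; median −0.42, camera adjusted p = 0.00657, and adjusted p = 0.722 with an estimated correlation). Without wild-type water replicate 2 the camera adjusted p of the Wnt targets was 0.0671. Among 26 senescence core genes CDKN2B, the CDK inhibitor p15, rose from 1.03 to 3.06 FPKM and 0 fell (2 adjusted over the list alone; camera adjusted p = 0.126). CDKN1A, the CDK inhibitor p21, stood at 6.49 ± 3.42 and 11.6 ± 1.26 FPKM (adjusted p = 0.373), and LMNB1, lamin B1, at 4.60 and 3.27 FPKM (adjusted p = 0.449).

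Of 24 p53 targets 1 rose in wild-type cells, the stress protein gene GADD45A from 9.48 to 26.4 FPKM (3 adjusted over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.573 with an estimated correlation). This list lost its call without wild-type water replicate 2 (adjusted p = 0.113) or wild-type HU replicate 2 (adjusted p = 0.0833). Of 20 colon epithelial genes 4 rose, among them the mucosal peptide gene TFF3 from 21.4 to 42.0 FPKM and the adhesion gene CEACAM1 from 1.09 to 4.17 FPKM (5 adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.722 with an estimated correlation), a call lost without wild-type water replicate 2 (adjusted p = 0.106). No member changed among 16 cGAS-STING and RNA-sensing components (camera adjusted p = 0.535), 13 mesenchymal, 29 lysosomal, 24 cholesterol synthesis, 25 hypoxia and glycolysis, 45 ribosomal protein or 15 early stress genes.

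The largest changes with HU in wild-type cells lay outside these lists. KRTAP3-1, a keratin-associated protein, rose from 5.84 to 114 FPKM (log2 change 4.07, SE 0.17, limma adjusted p = 1.58e-04), and LGALS1, galectin 1, rose 8.52-fold from 37.1 ± 8.46 FPKM. TXNIP, an inhibitor of thioredoxin, rose from 3.43 to 30.3 FPKM. IGFL1, a secreted IGF-like protein, and SPINK1, a trypsin inhibitor, rose from the floor, at least 30.8-fold and 18.9-fold. IL32, a cytokine gene, rose from 22.5 to 142 FPKM. The receptor tyrosine kinase gene KIT fell from 15.1 to 4.08 FPKM (log2 change −1.63, SE 0.22). Also lower were A2LD1 from 10.6 to 3.36 FPKM, SFXN2, a mitochondrial carrier, from 10.3 to 4.53 FPKM and RARRES2, the chemokine chemerin, from 94.1 to 48.5 FPKM. PRSS1, trypsin 1, fell from 137 to 43.2 FPKM, but it has near-identical copies and its value is uncertain. In all, 237 genes changed with HU in wild-type cells, 214 higher and 23 lower. Of these 90.3% were higher (70.1% after correction for GC content and length). At the unadjusted level 1992 genes had an unadjusted p under 0.05. Without wild-type water replicate 1 or 2 the count was 90 or 116, and without wild-type HU replicate 1 or 2 it was 27 or 17. Without either knockout HU library, which only add to the estimate of spread, it was 48. Of 30 changed genes named for this comparison 7 passed in each fit that left out 1 library: IGFL1, KRTAP3-1, LGALS1, SPINK1, TXNIP, RSAD2 and CEACAM1.

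**Figure D3:**
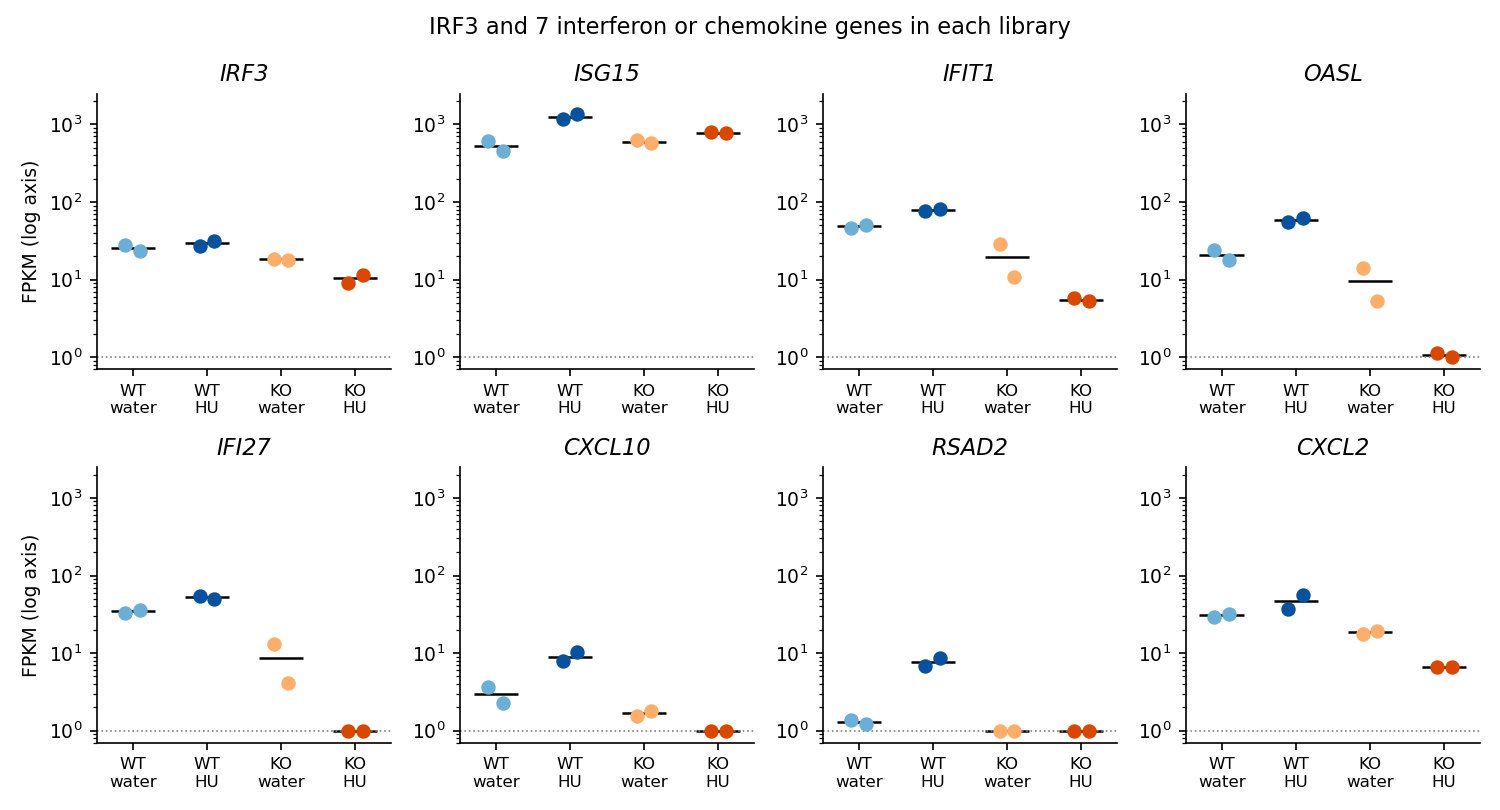
FPKM of IRF3 and 7 interferon-stimulated or chemokine genes in each library on a log axis, with the mean of each group as a bar and the floor of 1 FPKM dotted. After HU, OASL stood at 58.3 FPKM in wild-type cells and 1.07 in knockout cells, and CXCL10 at 9.01 FPKM and at the floor.

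In knockout cells HU changed 4109 genes, of which 34.0% were higher, a share that became 56.3% after quantile normalization, 50.0% after median-of-ratios scaling and 64.4% after GC and length correction. Genes of the lysosome fell in 20 of 29 cases, a list shift that passed only with the preset correlation. CTSD, cathepsin D, fell from 69.4 ± 50.1 to 8.12 ± 0.927 FPKM (mean ± SD, n = 2 libraries per group, log2 change −2.74, SE 0.44, limma adjusted p = 0.00500). FUCA1, an alpha-fucosidase gene, fell from 62.9 to 24.6 FPKM. Without knockout HU replicate 2 neither passed (adjusted p = 0.0528 for CTSD and 0.0609 for FUCA1). Replication genes fell in 31 of 53 cases and rose in 5, a list shift that also passed only with the preset correlation. CHAF1B, a histone chaperone, fell from 28.1 to 8.20 FPKM. POLA2, of DNA polymerase alpha, fell from 24.0 to 8.46 FPKM, and RRM2, a subunit of the enzyme that HU inhibits, from 585 to 308 FPKM (log2 change −0.93, SE 0.10). LGR5, a Wnt target and intestinal stem cell marker, fell from 19.8 to 1.24 FPKM (log2 change −3.16, SE 0.28). SPINK1 rose from 19.7 to 197 ± 38.1 FPKM and LGALS1 from 39.5 to 192 FPKM.

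Of 29 lysosomal genes 20 fell and 0 rose with HU in knockout cells (20 adjusted over the list alone; median −1.08 against −0.17 for all genes, camera adjusted p = 5.35e-04, and adjusted p = 0.722 with an estimated correlation). Of 53 G1/S and replication genes 31 fell and 5 rose (39 adjusted over the list alone; median −0.67, camera adjusted p = 8.73e-04, and adjusted p = 0.722 with an estimated correlation). Without knockout water replicate 1 this list had camera adjusted p = 0.0815. MCM2, of the replicative helicase, fell from 36.5 to 17.4 FPKM and E2F1, which activates these genes, from 8.08 to 3.58 FPKM. After correction for GC content and length their log2 changes of −1.01 and −0.97 became −0.25 (adjusted p = 0.108) and 0.10 (0.620). Mitotic genes went both ways, 11 higher and 18 lower of 50 (29 adjusted over the list alone; camera adjusted p = 0.907), with a median of −0.23 while the camera direction was upward. CKS2, a CDK-binding protein, rose from 847 to 2366 FPKM and PTTG1, securin, from 351 to 716 FPKM. The proliferation marker MKI67 fell from 13.5 to 5.71 FPKM and CCNA2, cyclin A2, from 93.2 to 60.6 FPKM. Of 26 senescence core genes 14 fell and 1 rose (16 adjusted over the list alone; camera adjusted p = 0.130). RB1 fell from 22.6 to 16.3 FPKM (log2 change −0.45, SE 0.13, adjusted p = 0.0366) and its relative RBL1 from 5.10 to 1.38 FPKM. The RB1 call was lost after quantile normalization (adjusted p = 0.319) or median-of-ratios scaling (0.220), and without any 1 library other than those of wild-type water (0.0574 to 0.172). The histone methyltransferase gene EZH2 fell from 41.9 to 19.0 FPKM. LMNB1 fell from 4.51 to 2.21 FPKM, a call lost under all 3 scalings (adjusted p = 0.330, 0.0739 and 0.356) and without any 1 of the same libraries as for RB1 (0.0525 to 0.194). CDKN1A stood at 15.3 ± 8.68 and 8.55 ± 1.06 FPKM (adjusted p = 0.248).

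Interferon-stimulated genes also went both ways with HU in knockout cells: 12 fell and 2 rose of 39 (14 adjusted over the list alone; median −0.43, camera adjusted p = 0.248). IFIT1 fell from 19.8 ± 12.6 to 5.50 ± 0.342 FPKM and LGALS3BP, a secreted glycoprotein, from 60.1 to 11.6 FPKM. The IFIT1 call was lost after quantile normalization (adjusted p = 0.0755) and without knockout HU replicate 1 or 2 (0.0873 and 0.106). Its log2 change of −1.54 became −0.88 without knockout water replicate 1 and −2.19 without replicate 2. ISG20 rose from 10.5 to 35.1 FPKM, and ISG15 stood at 598 and 786 FPKM (adjusted p = 0.0809, though it passed under 2 of the 3 scalings). IFNB1 and IL29 were at the floor in all 4 knockout libraries. Of 16 cGAS-STING and RNA-sensing components 3 fell and 0 rose (3 adjusted over the list alone; camera adjusted p = 0.216), including TMEM173, which encodes STING, from 5.4 to 2.1 FPKM and IRF3 itself (log2 change −0.77, SE 0.17, adjusted p = 0.0123). The TMEM173 change of −1.03 became −0.37 after GC and length correction (adjusted p = 0.0840). The IRF3 change was −0.46 after quantile normalization (adjusted p = 0.0976) and −0.14 after GC and length correction (0.540). Its adjusted p was 0.0670 without knockout water replicate 2 and 0.0943 or 0.0528 without knockout HU replicate 1 or 2. Of 29 secretory genes 10 fell and 2 rose (12 adjusted over the list alone; camera adjusted p = 0.268). GDF15, a stress cytokine, fell from 179 ± 89.7 to 41.7 FPKM and CXCL2, a neutrophil chemokine, from 18.5 to 6.6 FPKM, while MMP7, a matrix protease, rose from 1.00 to 2.68 FPKM. The median of this list was −0.37, but 0.01 after correction for GC content and length. NF-kB targets split evenly, 3 higher and 3 lower of 21 (6 adjusted over the list alone; camera adjusted p = 0.990), with a median of −0.31 that turned to 0.01 under quantile normalization and 0.20 after GC and length correction.

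Of 20 MHC class I presentation genes 10 fell and 4 rose (17 adjusted over the list alone; median −0.91, camera adjusted p = 0.268). B2M rose from 836 to 2851 FPKM, while the endoplasmic reticulum chaperones CALR and PDIA3 fell, from 172 to 23.4 FPKM and from 94.1 to 18.2 FPKM. Of 15 Wnt targets 7 fell and 0 rose (8 adjusted over the list alone; median −0.79, camera adjusted p = 0.0199, and adjusted p = 0.722 with an estimated correlation), among them the transcription factors LEF1 and MYC, from 10.8 to 3.68 FPKM and from 42.4 to 16.9 FPKM. Correction for GC content and length left a Wnt median of −0.06 (camera adjusted p = 0.366), and without knockout water replicate 2 the adjusted p was 0.0976. Of 45 ribosomal protein genes 18 rose and 6 fell (26 adjusted over the list alone; median 0.26, camera adjusted p = 0.0014, and adjusted p = 0.776 with an estimated correlation). RPS27 stood at 7632 and 16074 FPKM and RPL30 at 3926 and 7670 FPKM. Quantile normalization turned this median to −0.15. Of 20 colon epithelial genes 8 fell and 3 rose (11 adjusted over the list alone; camera adjusted p = 0.990). EPCAM, an adhesion protein, fell from 469 ± 147 to 149 FPKM. TFF3 rose from 25.7 to 56.5 FPKM and KRT20, a keratin of differentiated intestinal cells, from 20.7 to 36.6 FPKM. DDIT3 rose 2.60-fold. In contrast, 14 of 26 integrated stress response genes fell and 2 rose (17 adjusted over the list alone; camera adjusted p = 0.231). No shift of the list passed for cholesterol synthesis genes (11 lower and 1 higher of 24, median −0.69), hypoxia and glycolysis genes (7 lower of 25), p53 targets (4 higher and 3 lower of 24), homologous recombination genes (4 higher and 11 lower of 32), mesenchymal genes (4 lower of 13) or early stress genes (1 higher and 7 lower of 15).

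Other large changes in knockout cells were rises of C15orf48, of the mitochondrial respiratory chain, from 30.5 to 173 FPKM, SUN3 from 2.68 to 16.9 FPKM and GAST, gastrin, from 2.28 to 14.7 FPKM. TXNDC5, a protein disulfide isomerase, fell from 37.9 ± 20.1 to 2.89 ± 2.67 FPKM and ASNA1, which inserts tail-anchored proteins, from 94.5 ± 43.9 to 9.0 FPKM. HNRNPA1P10 fell from 25.8 FPKM to the floor, but as a pseudogene it shares reads with its parent. Of the 4109 changed genes 1397 were higher and 2712 lower, and 5368 had an unadjusted p under 0.05. The median over all genes was −0.17, against 0.01 after quantile normalization, −0.01 after median-of-ratios scaling and 0.10 after GC and length correction. The count was 2040 without knockout water replicate 2, and 1273 or 657 without knockout HU replicate 1 or 2. Of 45 changed genes named for this comparison 27 passed in each fit that left out 1 library. The others were ASNA1, CCNA2, CTSD, E2F1, EPCAM, FUCA1, GAST, GDF15, HNRNPA1P10, IFIT1, IRF3, KRT20, LMNB1, MCM2, MKI67, MYC, RB1 and TMEM173. Under each of the 3 scalings 36 passed, the others being RB1, LMNB1, IRF3, TMEM173, IFIT1, E2F1, MCM2, CCNA2 and HNRNPA1P10. The choice of named genes favours their passing, so these shares do not hold for all changed genes.

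The HU effects of the 2 genotypes correlated across genes (Pearson r = 0.55, Spearman rho = 0.55; genes are not independent replicates, and the groups share no library). Without wild-type water replicate 1 Pearson r was 0.44. HU raised 129 genes in both genotypes, against 25.7 for independent lists, and lowered 15 in both, against 5.36, while 4 genes changed in opposite directions. Both lists used the same estimate of spread for each gene, which can raise their overlap, and the wild-type list depended on single libraries. LGALS1, SPINK1, ISG20, SOD2, BIRC3, DDIT3, TFF3 and B2M were among those raised in both.

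Without HU, 208 genes differed between knockout and wild-type cells. KRT20 was at the floor in wild-type water and at 20.7 ± 1.74 FPKM in knockout water, at least 20.7-fold higher (n = 2 libraries per group; log2 change 3.44, SE 0.14, limma adjusted p = 1.08e-04). GPX3, an extracellular glutathione peroxidase, and SPINK1 were likewise at least 31.6-fold and 19.7-fold higher. UCA1, a long noncoding RNA, rose 11.8-fold from 5.93 FPKM. The transcribed pseudogene SFTA1P stood at 1.59 and 22.4 FPKM, uncertain values since reads may be shared, and KRTAP3-1 at 5.84 and 54.0 FPKM. S100A4, a calcium-binding protein tied to cell motility, was lower in knockout water at 319 ± 166 FPKM against 1274 ± 9.52 (log2 change −2.10, SE 0.31, adjusted p = 0.0235). Also lower were C6orf15, at 28.4 and 5.20 FPKM, and the calcitonin gene CALCA, at 9.17 and 2.17 FPKM. ACOT4, an acyl-CoA thioesterase, stood at 5.55 and 1.03 FPKM and ACN9 at 10.3 and 1.84 FPKM.

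Of 39 interferon-stimulated genes 2 were lower and 1 was higher in knockout water (5 adjusted over the list alone; median −0.17, camera adjusted p = 4.67e-05, and adjusted p = 0.24 with an estimated correlation). OAS1, an antiviral RNA sensor, stood at 36.7 FPKM in wild-type and 18.8 in knockout water, IFI44 at 2.70 FPKM and the floor, and IFI35 at 1.03 and 3.28 FPKM. IFIT1 was at 48.8 ± 2.91 and 19.8 ± 12.6 FPKM (adjusted p = 0.0956), ISG15 at 534 and 598 FPKM (adjusted p = 0.584) and CXCL10 at 2.97 and 1.69 FPKM (adjusted p = 0.255). None of 24 cholesterol synthesis genes passed limma (0 adjusted over the list alone; median −0.24, camera adjusted p = 0.00339, and adjusted p = 0.722 with an estimated correlation). Nor did any of 15 Wnt targets (2 adjusted over the list alone; median −0.35, camera adjusted p = 0.0192, and adjusted p = 0.722 with an estimated correlation). Of 53 G1/S genes only CCNE1, cyclin E1, changed, from 21.1 to 37.8 FPKM, although the list shifted downward (2 adjusted over the list alone; median −0.07, camera adjusted p = 0.00657, and adjusted p = 0.722 with an estimated correlation). Of 50 mitotic genes only UBE2C, a ubiquitin-conjugating enzyme, changed, from 474 to 754 FPKM (1 adjusted over the list alone; median −0.13, camera adjusted p = 0.0014, and adjusted p = 0.722 with an estimated correlation). Ribosomal protein genes had a median of −0.05 and 0 calls among 45 members (0 adjusted over the list alone; camera adjusted p = 0.0360, and adjusted p = 0.812 with an estimated correlation).

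Several of these genotype calls on lists rested on single libraries. Without knockout water replicate 2 the camera adjusted p was 0.311 for mitotic, 0.129 for G1/S and 0.804 for ribosomal protein genes, and without replicate 1 it was 0.588 for Wnt targets, whose median turned to 0.03, and 0.143 for cholesterol synthesis genes. Without wild-type water replicate 1 it was 0.0736 for G1/S and 0.590 for ribosomal protein genes, and without replicate 2 it was 0.0845 for Wnt targets and 0.136 for cholesterol synthesis genes. Lists whose shift did not pass still held changed genes: CSF2 rose from 3.52 to 10.0 FPKM, TNFAIP8, an NF-kB target, from 5.16 to 12.5 FPKM and GADD45A from 9.48 to 18.2 FPKM. PSMB9, an immunoproteasome subunit, rose from 18.9 to 45.6 FPKM and DDIT3 from 69.0 to 182 FPKM, while NUPR1, a stress-induced chromatin protein, fell from 16.5 to 6.54 FPKM. CDKN1A stood at 6.49 ± 3.42 FPKM in wild-type and 15.3 ± 8.68 in knockout water (adjusted p = 0.225). The senescence core (0 of 26), sensing component (0 of 16), mesenchymal (0 of 13), lysosomal (0 of 29), hypoxia (0 of 25), recombination (0 of 32) and early stress (0 of 15) lists held no changed gene.

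Of the 208 genes that differed between the genotypes in water 153 were higher and 55 lower in knockout cells, and 2080 had an unadjusted p under 0.05. The share of higher calls was 73.6%, against 59.5% after quantile normalization, 59.5% after median-of-ratios scaling and 57.1% after GC and length correction. Leaving out 1 library gave 1108 genes without knockout water replicate 1 and 8 without replicate 2, 23 without wild-type water replicate 2, 17 without either wild-type HU library and 9 without either knockout HU library. Of 22 changed genes named for this comparison 5 passed in every such fit: KRT20, GPX3, UCA1, SPINK1 and SFTA1P. Under each of the 3 scalings 19 passed, the others being NUPR1, TNFAIP8 and UBE2C. With only the water libraries fitted, 0 genes passed.

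After HU, 26 of 39 interferon-stimulated genes, 18 of 29 secretory genes and 19 of 29 lysosomal genes were lower in knockout than in wild-type cells. OASL, an antiviral relative of the OAS enzymes, stood at 58.3 ± 4.82 FPKM in wild-type and 1.07 ± 0.0975 in knockout cells (mean ± SD, n = 2 libraries per group; log2 change −4.84, SE 0.37, limma adjusted p = 9.50e-04). IFI27, a mitochondrial interferon-induced protein, was at 52.4 FPKM and the floor, at least 52.4-fold lower, and IFIT1 and IFIT2 were 14.5-fold and 14.4-fold lower. RSAD2, IFI44 and CXCL10 were at the floor in knockout cells and at 7.80, 5.83 and 9.01 FPKM in wild-type cells. IL29 and IFNB1 were at the floor in knockout cells too, and at 2.89 and 1.66 FPKM in wild-type cells. ISG15 was at 786 FPKM in knockout and 1264 in wild-type cells (log2 change −0.68, adjusted p = 0.0148). Of 39 interferon-stimulated genes 26 were lower and 1 was higher (29 adjusted over the list alone; median −0.68 against −0.14 for all genes, camera adjusted p = 6.94e-07, and adjusted p = 0.24 with an estimated correlation). After correction for GC content and length 22 were lower and 1 was higher. Without wild-type HU replicate 1 or knockout HU replicate 2, 12 and 11 were lower, while the list kept its call at the preset correlation.

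Of 29 secretory genes 18 were lower and 1 was higher in knockout cells after HU (20 adjusted over the list alone; median −1.06, camera adjusted p = 0.00197, and adjusted p = 0.722 with an estimated correlation). CXCL2 stood at 46.5 FPKM in wild-type and 6.6 in knockout cells, CXCL3 at 20.2 and 1.95 FPKM, IL8 at 77.7 and 22.6 FPKM and GDF15 at 158 and 41.7 FPKM. MMP7 was at the floor in wild-type cells and at 2.68 FPKM in knockout cells. Of 29 lysosomal genes 19 were lower (22 adjusted over the list alone; median −0.96, camera adjusted p = 1.07e-04, and adjusted p = 0.722 with an estimated correlation). FUCA1 stood at 85.9 and 24.6 FPKM and the cathepsin B gene CTSB at 67.3 and 14.9 FPKM. After GC and length correction the lysosomal median was −0.71 and 16 members were lower. Without any 1 of the 4 HU libraries 5 to 9 secretory and 1 to 6 lysosomal genes were lower, while both lists kept their calls at the preset correlation. Of 24 cholesterol synthesis genes 13 were lower and 1 was higher (17 adjusted over the list alone; median −0.68, camera adjusted p = 0.0014, and adjusted p = 0.722 with an estimated correlation). Among them DHCR7, a reductase of the pathway, stood at 25.8 and 5.45 FPKM.

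Of 25 hypoxia and glycolysis genes 11 were lower in knockout cells after HU (11 adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.722 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase, stood at 9.74 and 1.95 FPKM and the glycolytic enzyme gene ENO1 at 1213 and 587 FPKM. Of 26 integrated stress response genes 13 were lower and 2 higher (18 adjusted over the list alone; camera adjusted p = 0.0345, and adjusted p = 0.722 with an estimated correlation). NUPR1 stood at 32.0 and 3.49 FPKM, DDIT4, an inhibitor of mTORC1, at 31.9 and 8.94 FPKM and DDIT3 at 189 and 472 FPKM. The call on this list was lost without wild-type HU replicate 2 (adjusted p = 0.0764), either wild-type water library (0.0537 and 0.0556) or either knockout water library (0.0519 and 0.0505). Of 15 Wnt targets 5 were lower (5 adjusted over the list alone; median −0.63, camera adjusted p = 0.0335, and adjusted p = 0.722 with an estimated correlation). LGR5 stood at 15.6 and 1.24 FPKM and LEF1 at 13.1 and 3.68 FPKM. GC and length correction turned this median to 0.09 (adjusted p = 0.309), and the adjusted p was 0.0987 without wild-type HU replicate 2 and 0.0709 without knockout HU replicate 1. Of 45 ribosomal protein genes 12 were higher and 6 lower (18 adjusted over the list alone; median 0.14, camera adjusted p = 0.0189, and adjusted p = 0.812 with an estimated correlation). RPS27 stood at 7845 and 16074 FPKM. Quantile normalization turned the ribosomal median to −0.09, and the adjusted p was 0.145 without wild-type HU replicate 1 and 0.0747 without knockout HU replicate 2.

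For the other lists no shift between the genotypes after HU passed camera, although they held changed members and some had medians far from the −0.14 of all genes. Of 20 MHC class I presentation genes 12 were lower and 4 higher (17 adjusted over the list alone; median −1.12, camera adjusted p = 0.168). B2M was 2.29-fold and PSMB9 2.41-fold higher and CALR 6.74-fold lower in knockout cells. Of 53 G1/S genes 20 were lower and 5 higher (31 adjusted over the list alone; camera adjusted p = 0.125). PCNA, the sliding clamp of DNA polymerase, stood at 396 FPKM in wild-type and 750 in knockout cells and RPA3 at 54.4 and 120 FPKM, but the helicase subunit gene MCM7 at 83.9 and 35.2 FPKM. MKI67 stood at 11.9 and 5.71 FPKM among 50 mitotic genes, of which 14 were lower and 10 higher (30 adjusted over the list alone; camera adjusted p = 0.931). TMEM173 stood at 4.73 and 2.1 FPKM, and the IRF3 kinase gene IKBKE at 5.02 and 2.09 FPKM, among 5 lower of 16 sensing components (5 adjusted over the list alone; camera adjusted p = 0.551). NF-kB targets (7 lower and 2 higher of 21), colon epithelial genes (11 lower and 2 higher of 20, median −0.86), senescence core genes (7 lower and 1 higher of 26), p53 targets (3 each way of 24), recombination genes (6 lower and 4 higher of 32), mesenchymal genes (4 lower of 13) and early stress genes (4 lower and 2 higher of 15) had no shift that passed.

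Among single genes, KRT20 was at least 36.6-fold higher in knockout cells after HU (log2 change 4.23, SE 0.14, limma adjusted p = 4.62e-05), SPINK1 10.4-fold and LY96, a partner of Toll-like receptor 4, 12.5-fold. S100A4 stood at 1378 and 53.5 FPKM and IGFL1 at 30.8 and 1.06 FPKM. GPX3, at least 16.5-fold, and SFTA1P, 8.76-fold, were again higher, and so was the pseudogene NCOR1P1, whose reads its parent shares. In all 3544 genes differed, 1313 higher and 2231 lower, and 4974 had an unadjusted p under 0.05. The all-gene median of −0.14 became 0.01 after quantile normalization, −0.01 after median-of-ratios scaling and 0.09 after GC and length correction, and the share of higher calls went from 37.1% to 55.9%, 51.4% and 62.0%. The count was 518 or 1140 without wild-type HU replicate 1 or 2, and 1092 or 514 without knockout HU replicate 1 or 2. Of 44 changed genes named for this comparison 37 passed in each fit that left out 1 library, the others being ISG15, IFNB1, GDF15, CTSB, MKI67, TMEM173 and IKBKE. ISG15, TMEM173 and IKBKE also failed under at least 1 of the 3 scalings. The choice of named genes favours their passing, so these shares do not hold for all changed genes.

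**Figure D4:**
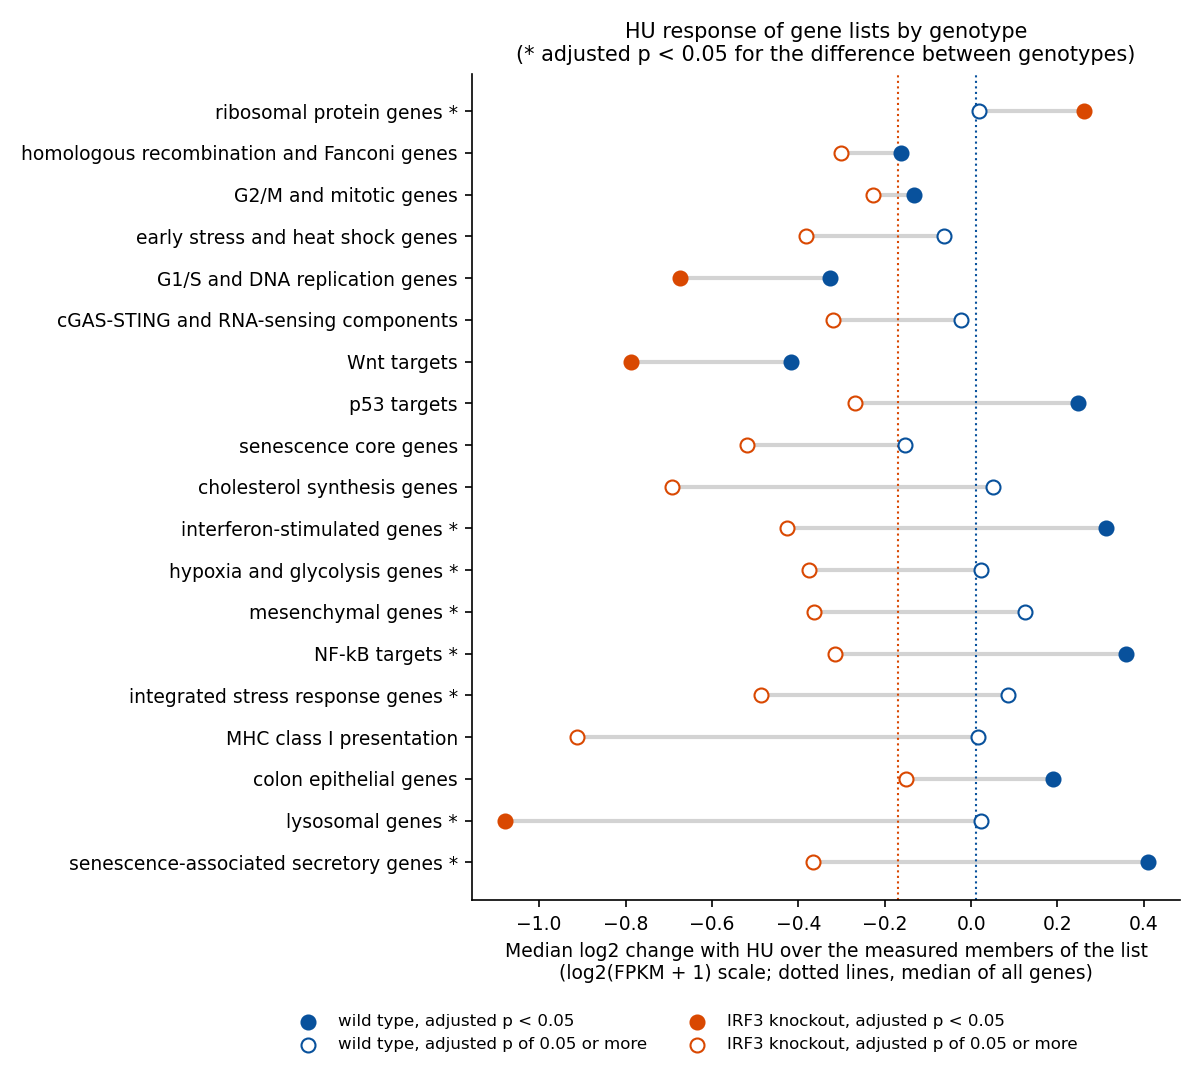
Median log2 change with HU over the measured members of each gene list in wild-type and in knockout cells; filled points passed camera with the preset correlation (none passed with an estimated one), stars mark lists whose difference passed, and dotted lines give the median of all genes. Secretory genes had medians of 0.41 in wild-type and −0.37 in knockout cells, the latter 0.01 after GC and length correction, and lysosomal genes 0.02 and −1.08, the former −0.03 after median-of-ratios scaling and −0.01 after quantile normalization.

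Whether the HU response depended on genotype was tested as the difference of the HU effects, knockout minus wild type. IGFL1 responded in wild-type cells, from the floor to 30.8 FPKM, and stood at the floor or near it in knockout cells (difference −3.95, SE 0.21, n = 2 libraries per group, limma adjusted p = 0.00172). KRTAP3-1 rose from 5.84 to 114 FPKM in wild-type cells and stood at 54.0 and 95.8 FPKM in knockout water and HU (difference −3.25, SE 0.25, adjusted p = 0.0104). Its genotypes differed in water (log2 change 3.02) but did not pass after HU (−0.23, adjusted p = 0.350). LOC730755, which lay outside the rule for named genes and was chosen after its values were seen, stood at 3.18 and 22.1 FPKM in wild-type and 19.0 and 9.19 in knockout cells (difference −3.42). Near-identical copies of LOC730755 were not searched for, so its values are uncertain. With 1 of the 8 libraries left out, IGFL1 passed in all 8 fits, KRTAP3-1 in 3 (adjusted p up to 0.133) and LOC730755 in 1 (up to 0.260). These 3 were the only calls, all negative, while 3018 genes had an unadjusted p under 0.05 and the all-gene median was −0.23 (0.01 after quantile normalization, −0.03 after median-of-ratios scaling and 0.08 after GC and length correction). No interferon-stimulated gene passed over all genes: OASL had a difference of −3.70 (SE 0.52, adjusted p = 0.0863), RSAD2 −1.92 (adjusted p = 0.0811), CXCL10 −1.77 (adjusted p = 0.0863), IFIT1 −2.23 (adjusted p = 0.0880) and ISG15 −0.86 (adjusted p = 0.0920). CXCL2 (−1.92), CSF2 (−1.90), GDF15 (−2.36) and LGR5 (−2.28) all had adjusted p = 0.0863. OASL, RSAD2, CXCL10, CXCL2, CSF2, GDF15 and LGR5 each passed under 1 of the 3 scalings, and IFIT1 and ISG15 under 0.

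Several lists differed in their HU response. Of 39 interferon-stimulated genes 0 passed over all genes and 17 passed when adjusted over the list alone (median difference −0.56, camera adjusted p = 6.54e-05, and adjusted p = 0.24 with an estimated correlation). Of 29 secretory genes 18 passed when adjusted over the list alone (median −1.15, camera adjusted p = 0.0014), and of 29 lysosomal genes 19 (median −1.09, camera adjusted p = 1.89e-04), both with adjusted p = 0.722 with an estimated correlation. NF-kB targets (5 of 21 adjusted over the list alone; median −0.65, camera adjusted p = 0.0113), integrated stress response genes (12 of 26; −0.67, 0.0199), hypoxia and glycolysis genes (9 of 25; −0.59, 0.0192) and mesenchymal genes (4 of 13; −0.64, 0.0499) also had lower differences, each with adjusted p = 0.722 with an estimated correlation. Examples were RELB, an NF-kB subunit (−1.09), ATF3 (−1.52), ADM, the adrenomedullin gene (−2.02), and the matricellular gene CTGF (−1.77), none past the test over all genes. Ribosomal protein genes had a positive median of 0.16 (camera adjusted p = 6.54e-05, and adjusted p = 0.722 with an estimated correlation), which quantile normalization turned to −0.03. Differences did not pass for Wnt (camera adjusted p = 0.273), G1/S (0.925), senescence core (0.231), MHC class I (0.126, median −0.94), colon epithelial (0.0715, median −0.99) or cholesterol synthesis genes (0.115).

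Some of these calls were lost after GC and length correction or without single libraries. After the correction the median was −0.23 for NF-kB targets (camera adjusted p = 0.0706), −0.08 for hypoxia and glycolysis genes (0.0770) and −0.16 for mesenchymal genes (0.346), against 0.08 for all genes. Integrated stress response genes had −0.11 and kept their call (0.0335), and the interferon-stimulated, secretory and lysosomal medians were −0.25, −0.94 and −0.79. Without knockout water replicate 1 the adjusted p was 0.143 for integrated stress response genes and 0.150 for hypoxia genes, and without wild-type HU replicate 2 it was 0.0619 for the former. Without wild-type water replicate 2 it was 0.0505 for NF-kB targets and 0.0524 for hypoxia genes, and without replicate 1 it was 0.0948 for ribosomal protein genes. The mesenchymal call was lost without either wild-type water library (0.201 and 0.0524), knockout water library (0.0586 and 0.164) or knockout HU library (0.0928 and 0.0519). The count of genes was 2611 without knockout water replicate 1, 6 without replicate 2, and 1 without wild-type HU replicate 1.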

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

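Of the tests in this part, that of RNA mixing between knockout libraries was chosen only after the result was seen, as was the GC and length correction. The reading of the scaling test for interferon-stimulated genes was also set after its value was known.

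In the main fit, a test of the difference between the HU responses of the genotypes called 3 genes and 8 lists. None of the list tests passed with an estimated correlation. The NF-kB, hypoxia and mesenchymal lists also lost their call after GC and length correction. Quantile normalization turned the ribosomal protein median negative. The log2 differences, knockout minus wild type, were −3.95 for IGFL1, −3.25 for KRTAP3-1 and −3.42 for LOC730755. IGFL1 passed in all 8 fits that left out 1 library, KRTAP3-1 in 3 and LOC730755 in 1. Untreated knockout cells already held more of both less stable genes, KRTAP3-1 at 54.0 against 5.84 FPKM and LOC730755 at 19.0 against 3.18 FPKM. List medians were −0.56 for interferon-stimulated genes, −1.15 for secretory genes, −0.65 for NF-kB targets, −0.64 for mesenchymal genes, −1.09 for lysosomal genes, −0.67 for integrated stress response genes and −0.59 for hypoxia and glycolysis genes, against −0.23 for all genes. The ribosomal protein genes had 0.16.

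HU changed 4109 genes in knockout cells and 237 in wild-type cells. After removal of the trend on GC content and length, 4808 genes changed in knockout cells and 515 in wild-type cells. The correction also moved floor values, and it raised the count for genotype in water from 208 to 473, so it can add calls itself. The counts therefore cannot decide whether the trend caused the larger number, and they do not show that the same genes changed. Of the 4109 calls 2520 were among the 4808, and the share of higher calls went from 34.0% to 64.4%. Scaling between libraries as the whole cause is argued against by 3821 genes after median-of-ratios scaling. Fewer genes were called without knockout HU replicate 1 (1273) or replicate 2 (657), so the size of the count depends on single libraries. A stronger response of knockout cells to HU, a difference between the clones used and unrecorded differences in handling stay open and untested. The direct test of the difference called 3 genes, while 3018 had an unadjusted limma p under 0.05. In the simulations it recovered 31.9% of changes of 1 log2 unit, against 77.9% for HU in wild-type cells. So few calls do not show that the genotypes responded alike.

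Knockout water replicate 1 lay between replicate 2 and the knockout HU libraries, at 0.348 of the way from the former to the latter. RNA of the knockout HU libraries mixed into it is argued against by unequal implied shares. The 191 genes lower after HU implied a share of 0.594 and the 11 higher genes 0.0913, a difference of 0.502 (95% interval 0.373 to 0.599). After GC and length correction the shares were 0.534 from 75 lower genes and 0.0879 from 12 higher genes. These genes were chosen by the replicate 2 values that the shares also use, and the higher genes are few. Removal of the GC and length trend moved the position from 0.348 to 0.299 (0.286 to 0.311). Replicate 2 alone sets the start of this scale, so its own noise puts any other replicate above 0. How far was not estimated, so the position cannot decide on the trend as the whole cause. These intervals resample genes, so they hold no spread between libraries or cultures. No biological explanation was tested, as both replicates carry the same labels, and a difference in RNA quality or in the state of the cultures may remain. Without this library 2611 genes, in place of 3, passed the test of the difference of the HU effects, and 1108, in place of 208, differed between the genotypes in water.

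Of 39 interferon-stimulated genes 26 were lower and 1 was higher in knockout than in wild-type cells after HU, with a list median of −0.68. The shift passed camera with the preset correlation only (adjusted p = 6.94e-07, and 0.24 with an estimated correlation). The GC and length trend is argued against as the cause, since this median lay at the 0.01 percentile of 10000 random lists matched on GC content, length and expression, the smallest they can give (random median −0.21, central 95% −0.40 to −0.03). For the difference of the HU effects the same percentile was 0.16. After median-of-ratios scaling the list median lay 0.51 below that of all genes (−0.51, 95% interval −1.15 to −0.30, resampling list members). Before it the medians were −0.68 for the list and −0.14 for all genes. Scaling as the cause would have needed a value above −0.1, and the interval just missed the bound of more than 0.3 below set beforehand for excluding it. A change of scale moves list members and all genes nearly alike, so this value hardly depends on scaling and cannot decide on it. The values show only that the list lay below all genes under either scale. Loss of IRF3 and a difference between the clones used, which the labels do not give, stay open and untested.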

How the results depend on the processing

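The GC and length correction, the restriction to genes above the floor, the crossed pairing, the filters and the fit of only the compared groups for the IRF3 level, and quantile normalization and left-out libraries for the correlation were chosen after seeing the data. Of the 95 list results under the alternatives, 1763 values kept their side of the threshold, 85 lost a call, 46 gained one and 6 reversed with a call before or after. For the named genes these numbers were 2863, 408, 48 and 2. Among values that kept their side, 91 medians of lists without a call and 3 changes of genes without one (ISG15 for genotype in water, CDKN1A for HU in knockout cells) had the other sign, and so did 2 medians among lost list calls and 7 among gained ones.

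The count of genes changed with HU in wild-type cells (237) became 515 after GC and length correction and 0 when only the compared libraries were fitted, which leaves 2 residual degrees of freedom. The same fit gave 2159 for HU in knockout cells (4109), 0 for genotype in water (208) and 4729 for genotype after HU (3544). Replicates differed by a median of 0.24 and 0.25 log2 units in the water groups and 0.11 and 0.12 in the HU groups. The spread shared in the main fit can therefore understate the error of the comparison in water. Genotype in water also gave 341 at a filter of 5 FPKM, 473 after GC and length correction and 317 for genes above the floor. The difference of the HU effects (3) gave 384 at that filter, 7 with quantile normalization, 1 without trend and robust prior, 259 after GC and length correction and 135 for genes above the floor. Fewer genes tested ease the adjustment, but otherwise the cause was not tested. With an estimated correlation 0 of 35 list calls held.

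No clear pairing by replicate number was seen: deviations of same-numbered libraries correlated between −0.19 (wild-type water and HU) and 0.16 (knockout water and HU). These values cannot show whether same-numbered samples were prepared together. With the number as a block, 118 genes changed with HU in wild-type cells, 54 with genotype in water and 1 in the difference. With the numbers of wild-type water crossed, 147 and 134 genes were called in the first 2 comparisons.

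Leaving out 1 library gave 17 to 259 genes for HU in wild-type cells, 657 to 5280 for HU in knockout cells, 8 to 1108 for genotype in water, 514 to 4091 for genotype after HU and 1 to 2611 for the difference, with 28 to 35 list calls. The correlation of HU effects ranged from 0.44 to 0.58, and IRF3 from −0.60 to −0.32 in water and from −1.58 to −1.26 after HU, on the same side of the threshold throughout. The ribosomal protein genes reversed under quantile normalization to −0.15 (HU in knockout), −0.0925 (genotype after HU) and −0.0317 (difference). Without 1 library their median ranged from −0.0887 to 0.15 for HU in wild type, the latter without wild-type water replicate 1, and from −0.13 to 0.0354 for genotype in water, where it turned positive without that library or knockout water replicate 2 (0.0214). E2F1 reversed to 0.10 with HU in knockout cells after GC and length correction, and IL29, at the floor in every knockout library, moved to 0.40 there, since the correction moves floor values. Testing without the filter of 1 FPKM changed nothing, since it had removed no gene, while the filter of 5 FPKM left 7411 genes. Unknown depth and the floor limit genes of low expression.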

Other observations

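The comparison of untreated knockout cells with the HU response of wild-type cells was chosen only after the result was seen.

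Some of the genes that HU changed in wild-type cells also differed between untreated knockout and wild-type cells. Of 214 genes raised by HU in wild-type cells 48 were also higher in knockout than in wild-type water, against 2.81 for independent lists, and 8 of 23 lowered genes were also lower, against 0.109. These lists depend on single libraries: leaving out 1 gave 17 to 259 genes for HU in wild-type cells and 8 to 1108 for genotype in water. SPINK1, at the floor in wild-type water, stood at 18.9 FPKM in wild-type HU and 19.7 FPKM in knockout water, KRTAP3-1 at 114 and 54.0 FPKM, DDIT3 at 189 and 182 FPKM and GADD45A at 26.4 and 18.2 FPKM. IGFL1 was an exception, at 30.8 FPKM in wild-type HU and the floor in knockout water.

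Both comparisons use the wild-type water libraries, which links them without any effect. The covariance of the fold changes across genes was 0.0517, above the mean of 0.0406 and the highest of 0.0483 in 100 simulations of unchanged groups against those libraries, in which genes varied independently. With 1 wild-type water library as the control of each comparison it was −0.0203 or 0.0434, depending on which served which, and −0.0027 or 0.0421 after GC and length correction. The correlation was 0.39, against 0.59 in the simulations. The highest simulated overlap was 7 genes, but a mean of only 1.6 genes was raised by HU there, so this sets no bound where effects are real. A shared difference and the shared libraries therefore cannot be told apart across genes, since the sign of the covariance turned with the choice of control library.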
